A study of Mus musculus with 6 samples.

How the data were processed

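Total RNA of 5000 sorted bone marrow endothelial cells per sample was amplified with the Ovation Pico WTA kit, labelled with biotin and hybridised to microarrays, per the labels' protocols. The labels gave 6 arrays of male C57BL/6J mice, 3 of diabetic and 3 of nondiabetic mice, and carry the same diet text, 60 kcal% fat for 4 months, on all 6. The labels do not say whether the arrays of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. The authors deposited log2 expression values made with RMA (robust multi-array average), per the submitters' processing notes; RMA corrects background, sets the arrays to a common distribution and summarises probes to probe sets. The software, its version and the probe annotation used for RMA are not given in the sources used here. All values lay between 2.16 and 13.30, and the array medians between 5.21 and 5.28.

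The table held 41345 probe sets. Names came from the platform annotation supplied with the data, which can be old: 23521 probe sets named 1 gene, 1814 named several and 16010 had no name here. Of the former, 23328 matched the RefSeq gene table of assembly GRCm38.p6 by gene number, and that table was used for older and newer symbols of listed genes only. Each of 22180 genes took the value of the brightest of the probe sets that name it alone, by the mean over all 6 arrays, and 1082 genes had more than 1. Genes with a mean below the 40th percentile, a log2 value of 5.07, were left out as dim, which left 13308 tested genes and removed 8872.

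The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 6 arrays with no covariates, and p-values were adjusted by Benjamini and Hochberg over the tested genes with a threshold of 0.05. Intervals are 95% intervals from the same fit and are not adjusted. Differences are diabetic minus nondiabetic on the log2 scale. For single values per array an exact permutation test, two-sided, was used, and with 3 arrays against 3 its smallest possible p is 0.1. The median tested gene had a within-group SD of 0.24 and a standard error of 0.19.

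Before the data were examined, 36 gene lists were fixed: lists of endothelial, inflammatory, metabolic and stress genes, lists watched for RNA quality, and markers of the blood and stromal cells that a marrow endothelial sort could hold. Of 919 list entries, with a gene counted once for each list that holds it, 821 were measured. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the 36 lists. Camera with an estimated correlation and fry, directional, were run as alternatives. The genes named in the text were also chosen by a rule fixed before the data were examined: the 12 genes per direction with the smallest p among those whose groups do not overlap, passing over predicted genes and small RNAs (3 higher and 4 lower were passed over), 12 genes of the study's theme, and in each list the 2 tested members with the smallest p, with the member of highest mean for markers of other cells. Genes named outside this rule are pointed out.

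The alternatives were no filter on dim genes, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set as its own measurement, quantile normalization of the deposited values again, median centring, eBayes with trend and robust variances, array weights, a replicate block, and leaving out each array in turn. A fit with the mean of the pan-endothelial list per array as a covariate was added after seeing the data. The procedure was tested on simulated data with the spread of these arrays: of 200 genes changed among 13308, it recovered 63.4% of changes of 1 and 99.3% of changes of 2 on the log2 scale, with 6.35% and 5.34% of calls false. A simulated shift of 0.5 in the sinusoidal list had a camera adjusted p = 4.61e-09, and 1 unshifted list was called beside it. Probe sets with several names or none were left out of the tests and used only where stated.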

Results

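Endothelial cells were sorted from the bone marrow of male C57BL/6J mice and their RNA was profiled on microarrays. The diabetic group held 3 arrays, from mice with diabetes brought on by a high fat diet, and the nondiabetic group held 3 arrays. The labels of all 6 samples carry the same diet text, 60 kcal% fat for 4 months, so they do not settle what the nondiabetic mice ate. Each sample was a sort of 5000 cells. The median log2 value per array lay between 5.21 and 5.28, and the small number of arrays limited the precision. Across the 13308 tested genes, the correlation between arrays was 0.929 to 0.949 between the groups, 0.929 to 0.954 within the diabetic group and 0.937 to 0.944 within the nondiabetic group; these are correlations across genes, which are not independent replicates. The first principal component, 27.3% of the variance, placed 2 diabetic arrays at its ends, replicate 1 at -29.6 and replicate 3 at 29.9. The comparison asked which transcripts of marrow endothelium differ in diabetes, in a series concerned with the part this endothelium plays in the production of myeloid cells.

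A single gene, measured by 1 of its 2 probe sets, passed the test for the difference between diabetic and nondiabetic cells. Rabggtb, which encodes the beta subunit of the Rab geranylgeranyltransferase that attaches lipid anchors to Rab proteins, fell by 4.43 on the log2 scale (SE 0.20), from 7.75 ± 0.24 in nondiabetic to 3.32 ± 0.26 in diabetic cells (SD, n = 3 each). The diabetic values lay under the limit of 5.07 used for dim genes, where a probe set may show background alone, so the size of the fall is known only as a bound. The limma adjusted p was 0.000189. This value came from the only probe set that names Rabggtb alone, 17411319. The other probe set on the array that names Rabggtb, 17411304, also names the small nucleolar RNA Snord45c, and there the groups lay at 7.10 ± 0.26 and 7.40 ± 0.34, a difference of -0.29 (SE 0.22), so the 2 probe sets disagreed. At an adjusted p under 0.05, limma called 0 genes higher and 1 gene lower in diabetes, and the second smallest adjusted p was 0.302. At an unadjusted p under 0.05, 424 genes lay higher and 142 lower, 566 in all, where 665.4 would be reached by chance. All 3 diabetic arrays lay above all 3 nondiabetic arrays for 703 genes and below them for 355, together 7.95% of the tested genes, where chance gives 10%. The Rabggtb call was lost where the probe set was left out as dim, which happened with a filter at the 60th percentile and without nondiabetic replicate 3, where its difference was -4.30.

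**Figure D1:**
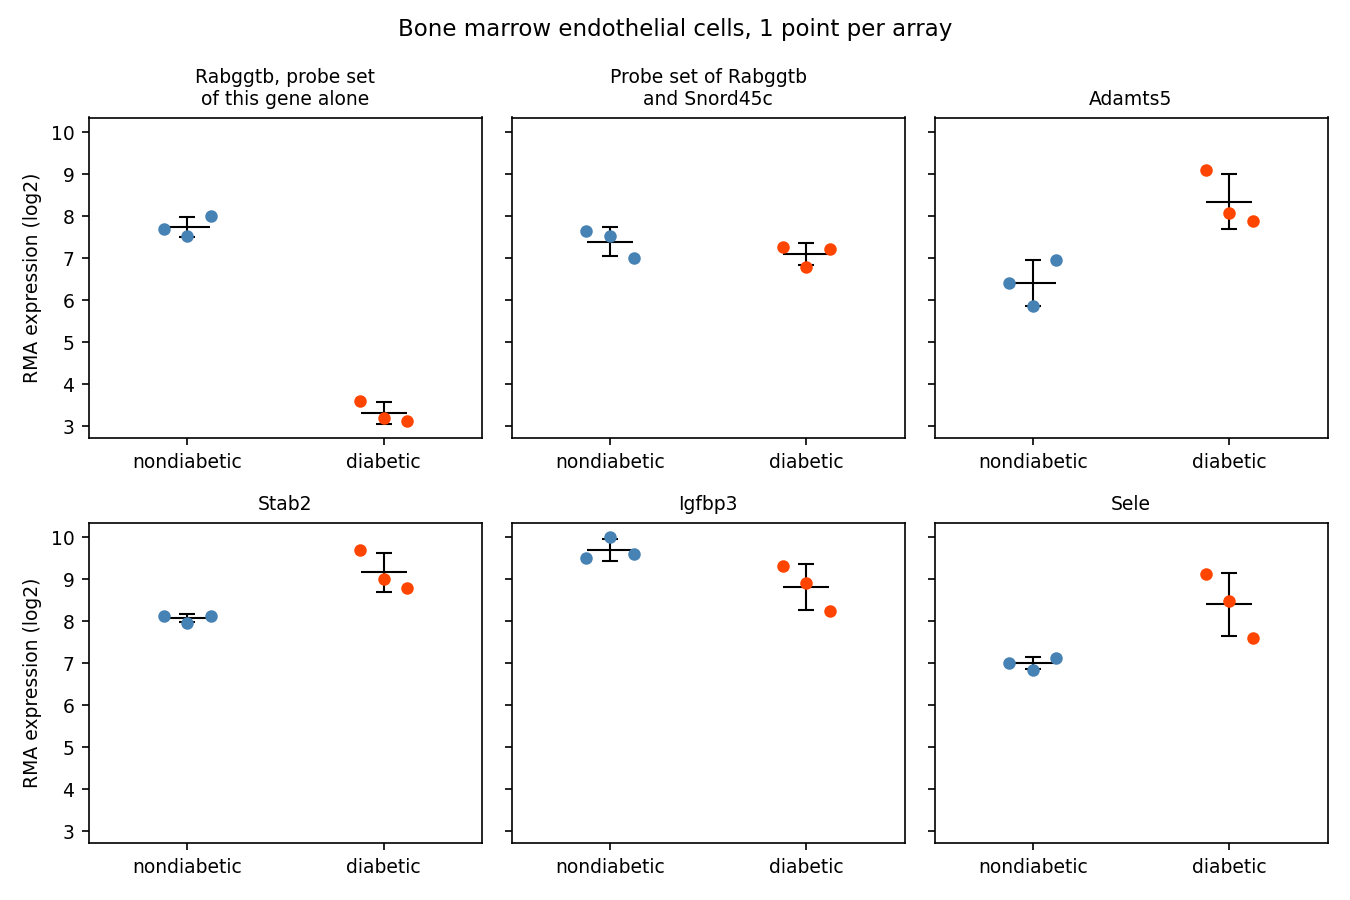
RMA expression (log2, vertical axis) of both Rabggtb probe sets and 4 further genes in nondiabetic and diabetic marrow endothelial cells, with 1 point per array, the group mean as a horizontal line and the SD as a bar (n = 3 each). The probe set of Rabggtb alone lay at 3.32 in diabetic and 7.75 in nondiabetic cells, while the probe set shared with Snord45c lay at 7.10 and 7.40; Adamts5, Stab2, Igfbp3 and Sele did not pass the adjusted test.

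The genes with the smallest p-values among those whose groups did not overlap are given as values only, since none but Rabggtb passed the adjusted test. Among those with higher values in diabetic cells, Rgs4, a regulator of G protein signaling, stood at 8.27 ± 0.77 against 6.13 ± 0.38 (SD, n = 3 each), a difference of 2.14 (SE 0.37) or 4.41-fold. Adamts5, a protease that cleaves aggrecan, stood at 8.35 ± 0.65 against 6.41 ± 0.55, a difference of 1.94 (SE 0.37). Il13ra1, a chain of the interleukin 13 receptor, differed by 1.11 (SE 0.20), and Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, by 1.10 (SE 0.19). Stab2, a scavenger receptor of sinusoidal endothelium that takes up hyaluronan, differed by 1.09 (SE 0.24). The differences of the zinc finger gene Zbtb39, the kinase gene Cdkl1, Ctsw, a protease of cytotoxic lymphocytes, and Col6a3, a collagen VI chain, were 1.60, 0.90, 0.88 and 0.80. Rnf7, a subunit of cullin ubiquitin ligases, Zfyve19 and Pgam2, a phosphoglycerate mutase of muscle, differed by 0.96, 0.76 and 0.73. Among the genes with lower values in diabetic cells, the difference was -0.90 (SE 0.24) for Cdc37l1, -0.80 (SE 0.20) for the hematopoietic nuclear protein gene Hemgn and -0.78 (SE 0.21) for Tmem47. Rce1, a protease that trims prenylated proteins, stood at 6.28 ± 0.12 against 6.97 ± 0.23, a difference of -0.69 (SE 0.17). Pcp4l1, Klhl8, Tril and Klhl28 differed by -0.76, -0.68, -0.68 and -0.66. Cenpq, a kinetochore gene, Zfp111 and Ormdl1, a regulator of sphingolipid synthesis, differed by -0.57, -0.56 and -0.54.

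The list of sinusoidal endothelial genes rose and the list of arteriolar endothelial genes fell in diabetic cells by camera at a preset correlation between genes, but neither was called by the other list tests tried. Of 17 tested sinusoidal genes, 13 had higher and 4 lower values in diabetic cells, and the mean log2 difference was 0.48 (adjusted p = 2.42e-05). Of 19 tested arteriolar genes, 3 had higher and 16 lower values, and the mean log2 difference was -0.29 (adjusted p = 2.42e-05). With an estimated correlation neither list was called, with an adjusted p = 0.849 for the sinusoidal and an adjusted p = 0.889 for the arteriolar list, and by fry these were 0.431 and 0.81. No member of either list passed the adjusted test over all genes; adjusted over the list alone, 5 sinusoidal genes and 0 arteriolar genes passed. These were Adamts5 and Stab2, given above, and Mrc1, the mannose receptor, which macrophages also carry, Abcc9, a subunit of potassium channels, and Gpr182, a receptor of sinusoidal endothelium. The latter genes, named here after their values were seen, differed by 0.99 (SE 0.27), 0.76 (SE 0.21) and 0.73 (SE 0.18). The arteriolar examples were Igfbp3, an insulin-like growth factor binding protein, at 8.83 ± 0.55 against 9.71 ± 0.26 (SD, n = 3 each), and Bmx, a kinase of arterial endothelium, which differed by -0.51 (SE 0.19). Per array, the sinusoidal mean was 7.99 ± 0.30 in diabetic and 7.51 ± 0.08 in nondiabetic cells, with all diabetic arrays above all nondiabetic arrays, and the arteriolar mean was 8.09 ± 0.36 and 8.38 ± 0.21, with overlap. The monocyte and neutrophil marker lists lay higher in the same diabetic arrays, by 0.31 and 0.31. Markers of endothelium in general did not pass the test: 26 genes had a mean log2 difference of -0.04 (adjusted p = 0.346), and among them Ptprb differed by -0.28 and Mmrn2 by 0.34. Diabetic replicate 1 stood apart in these markers, with a mean of 9.39 where the other diabetic arrays had 8.70 and 8.71. Without it the means of the sinusoidal, arteriolar and general lists were 0.30, -0.48 and -0.27, and the general list was called lower (adjusted p = 4.16e-05), as it was without nondiabetic replicate 3 (mean -0.16, adjusted p = 0.0192) and on all 6 arrays with array weights (mean -0.21, adjusted p = 0.00217). The arteriolar mean was -0.13 without diabetic replicate 3 and -0.19 without nondiabetic replicate 2, and both lists stayed called with every single array left out.

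**Figure D2:**
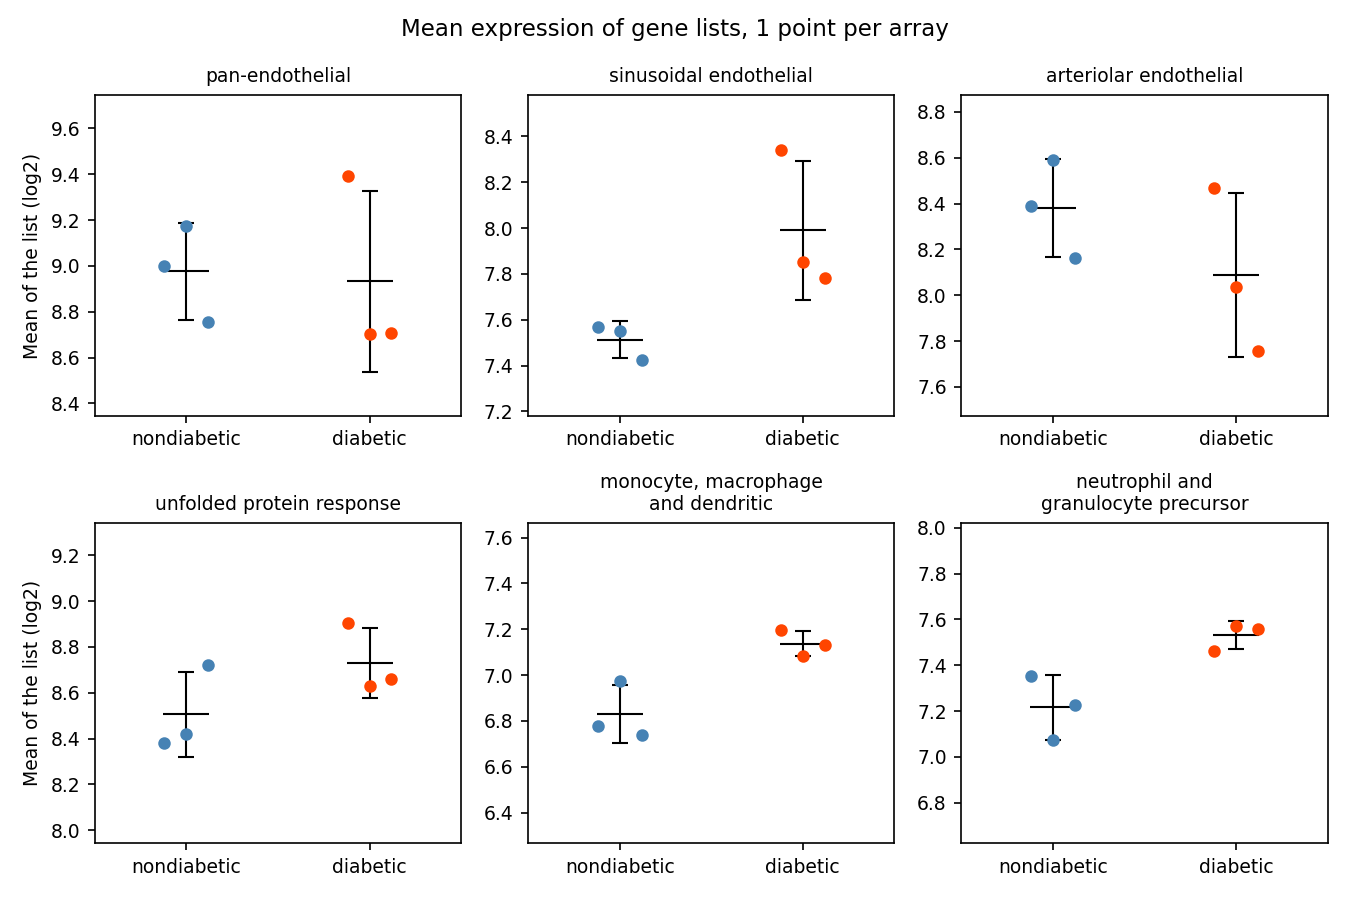
Mean log2 expression of the tested members of 6 gene lists (vertical axis, each panel spanning the same range of log2 units) in nondiabetic and diabetic cells, with 1 point per array, the group mean as a horizontal line and the SD as a bar (n = 3 each). The sinusoidal, monocyte and neutrophil means of all diabetic arrays lay above those of all nondiabetic arrays, while the pan-endothelial, arteriolar and unfolded protein response means overlapped.

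Markers of myeloid cells also rose as lists in the diabetic sorts. Of 17 tested monocyte, macrophage and dendritic genes 14 had higher values in diabetic cells, and the mean log2 difference was 0.31 (adjusted p = 0.000293, and adjusted p = 0.383 with an estimated correlation). Ms4a6c, a membrane protein of monocytes, differed by 0.68 (SE 0.19) and Ccr2, the chemokine receptor of inflammatory monocytes, by 0.50 (SE 0.18). Of 14 tested neutrophil and granulocyte precursor genes 12 had higher values, and the mean log2 difference was 0.31 (adjusted p = 0.0153, and adjusted p = 0.588 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, differed by 0.58 (SE 0.23), at 6.83 in diabetic and 6.26 in nondiabetic cells, with overlap. Lcn2, an iron-scavenging granule protein, differed by 0.58 (SE 0.25), at 6.08 in diabetic and 5.49 in nondiabetic cells. The nondiabetic Lcn2 level lay near the limit of 5.07 used for dim genes. With no filter on dim genes the mean of the neutrophil list was 0.15, and camera did not call it (adjusted p = 0.174). The neutrophil call ended without diabetic replicate 2 (adjusted p = 0.0799) and without nondiabetic replicate 2 (adjusted p = 0.265). In both groups the arrays held signal for genes of blood cells, chosen by the naming rule as the member of each list with the highest mean. Ly6c2 of the monocyte list stood at 11.09 ± 0.27 against 10.76 ± 0.44 in diabetic and nondiabetic cells (SD, n = 3 each). The mean level of that list was 6.98, so Ly6c2 alone does not show the amount of monocyte RNA. Mcpt8 of basophils stood at 11.25 ± 0.20 against 11.27 ± 0.30 and the platelet chemokine Ppbp at 11.39 ± 0.49 against 11.32 ± 0.47. Jchain, the joining chain of secreted antibodies, stood at 10.39 ± 0.53 against 10.15 ± 0.41. The mean levels of the neutrophil, megakaryocyte and B lymphoid lists, which hold these genes, were 7.37, 7.85 and 6.33. Mcpt8, Ppbp and Jchain alone therefore do not show the amount of such RNA either. The rule's picks Car1, Il7r and Ptprc stood lower, at 9.58 against 9.67, 9.04 against 8.54 and 9.13 against 8.96. The 12 tested B lymphoid genes had a mean log2 difference of 0.31 and did not pass (adjusted p = 0.0759), with differences of 0.90 for Dntt and 0.63 for Blnk. The markers of other cells had means of 0.22 for 14 megakaryocyte and platelet genes (adjusted p = 0.366), 0.08 for 13 pericyte and smooth muscle genes (0.515), 0.04 for 23 stem and progenitor genes (0.912) and 0.01 for 13 erythroid genes (0.912). For 11 mesenchymal stromal and osteoblast genes the mean was -0.05 (adjusted p = 0.515) and for 9 T and NK lymphoid genes it was -0.00078 (adjusted p = 0.473).

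Lists of leukocyte adhesion, endoplasmic reticulum stress, fatty acid handling and cell division genes rose in diabetic cells by the same test, beside the rise of the monocyte and neutrophil markers by 0.31 and 0.31. Of 21 tested leukocyte adhesion and chemokine genes 15 had higher values, and the mean log2 difference was 0.32 (adjusted p = 0.0247, and adjusted p = 0.913 with an estimated correlation). E-selectin (Sele), which captures rolling leukocytes, stood at 8.41 ± 0.75 against 7.00 ± 0.14 in diabetic and nondiabetic cells (SD, n = 3 each), a difference of 1.41 (SE 0.34) or 2.65-fold, and P-selectin (Selp) differed by 0.62 (SE 0.19). Of 24 tested unfolded protein response genes 22 had higher values, and the mean was 0.22 (adjusted p = 0.000293, and adjusted p = 0.903 with an estimated correlation). Its examples were Creld2, an endoplasmic reticulum chaperone, with a difference of 0.50 (SE 0.18), and the stress sensor kinase PERK (Eif2ak3), with 0.44 (SE 0.17). Plasma cells, which secrete protein in bulk, also carry much of this response. A list of 11 plasma cell genes chosen after seeing the data, 0 of them shared with it, had a mean 0.44 (SE 0.31) higher in the diabetic sorts. The groups overlapped (exact p = 0.2), and the mean was 0.25 higher without diabetic replicate 1. That list holds genes of secretory cells such as the chaperone gene Fkbp11, so it cannot tell plasma cell RNA from this response. Of 22 tested fatty acid handling and PPAR genes 20 had higher values, and the mean was 0.22 (adjusted p = 0.0148, and adjusted p = 0.903 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, differed by 0.76 (SE 0.23), and Cpt1a, which admits fatty acids to mitochondria, by 0.49 (SE 0.24). Of 38 tested cell cycle genes 29 had higher values, and the mean was 0.14 (adjusted p = 0.0247, and adjusted p = 0.903 with an estimated correlation). Its members with the smallest p-values went both ways, with 0.46 (SE 0.18) for the spindle checkpoint kinase Bub1 and -0.49 (SE 0.18) for the ribonucleotide reductase subunit Rrm2. With the mean of its 2 probe sets, Rrm2 differed by -0.11. Adjusted over the list alone or over all genes, 0 members of these lists and of the myeloid lists passed.

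Single arrays decided several of these calls. Without diabetic replicate 1 the means were 0.14 for adhesion (adjusted p = 0.388), 0.07 for fatty acid (0.35) and 0.08 for cell cycle genes (0.164), none of which was then called, and 0.14 for unfolded protein response genes, still called. Without nondiabetic replicate 1 the same 3 lists had means of 0.27, 0.18 and 0.11 and were not called, and without diabetic replicate 3 the fatty acid mean was 0.34 and the cell cycle list, with a mean of 0.16, was not called (adjusted p = 0.0532). The adhesion, fatty acid, cell cycle and neutrophil calls also ended with the filter at the 60th percentile, where the means were 0.37, 0.22, 0.15 and 0.33. Those of adhesion and neutrophil genes ended with every probe set kept (means 0.27 and 0.26), that of the neutrophil genes with no filter (mean 0.15) and that of the cell cycle genes with array weights (mean 0.09).

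**Figure D3:**
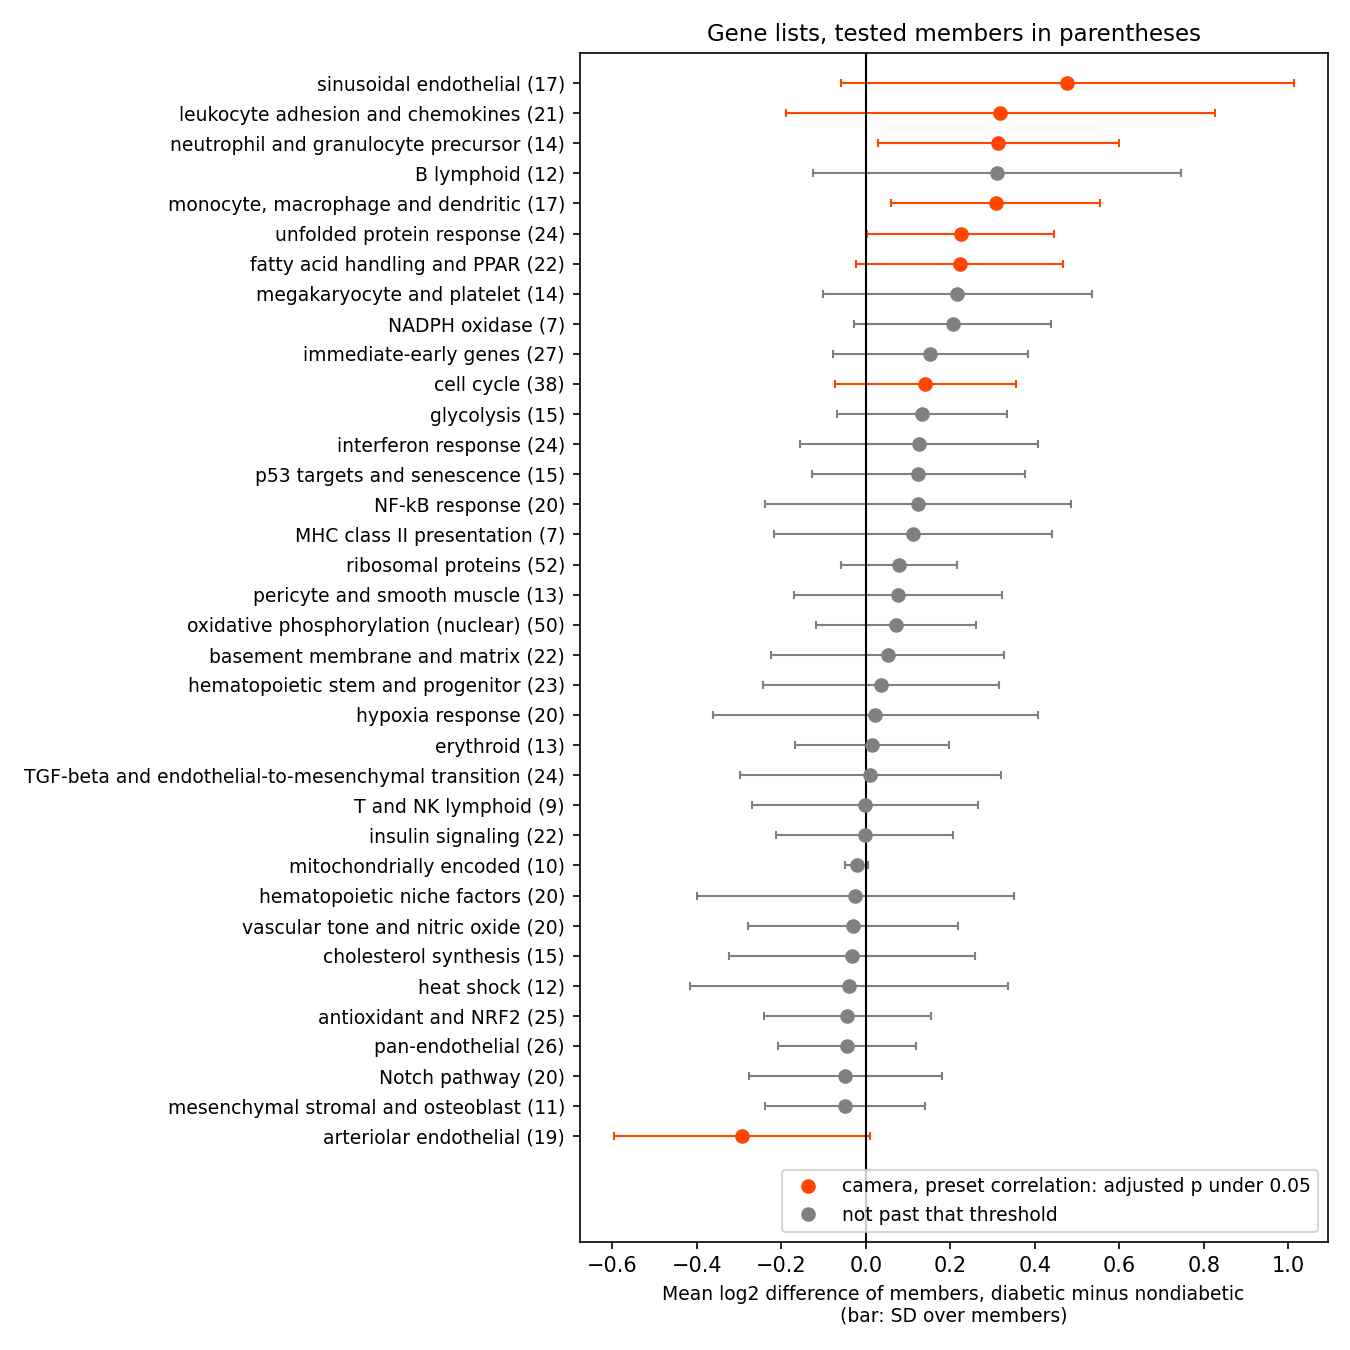
Mean log2 difference of the tested members of each of the 36 gene lists, diabetic minus nondiabetic (horizontal axis), with the number of tested members in parentheses and bars for the SD over members. Orange-red marks the 8 lists called by camera with its preset correlation, from the sinusoidal list at 0.48 to the arteriolar list at -0.29, and 0 lists were called with an estimated correlation.

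Genes by which marrow endothelium maintains blood stem and progenitor cells did not pass the test as a list, with 10 of 20 tested members higher and 10 lower and a mean of -0.03 (adjusted p = 0.566). Cxcl12, the chemokine that retains stem cells in the marrow, stood at 9.95 ± 0.18 against 10.24 ± 0.33 in diabetic and nondiabetic cells (SD, n = 3 each), and its difference of -0.29 had a 95% interval of -0.76 to 0.19. For stem cell factor (Kitl) the difference was -0.33 with an interval of -1.03 to 0.38, and for the adhesion molecule Vcam1 it was 0.93 with an interval of 0.22 to 1.64, before adjustment for the number of genes. Single arrays carried much of both, since Kitl differed by -0.0012 without diabetic replicate 3 and Vcam1 by 0.56 without diabetic replicate 1. The cytokine genes Csf1 and Il6 differed by 0.04 and 0.00645, with intervals of -0.54 to 0.62 and -0.56 to 0.58. Csf3, the granulocyte growth factor, was left out as dim, with log2 levels of 4.00 and 4.28. The adhesion gene Icam1 differed by 0.04, the transcription factor gene Egr1 by -0.08, the insulin receptor gene Insr by 0.02, the glutathione peroxidase gene Gpx1 by 0.11 and endothelial nitric oxide synthase (Nos3) by 0.16, and 0 of the theme genes passed the adjusted test. The signs of Csf1, Il6, Icam1, Egr1 and Insr were not stable under the alternatives tried, and the differences ranged from -0.46 to -0.14 for Cxcl12, 0.039 to 0.2 for Gpx1 and 0.072 to 0.26 for Nos3.

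The remaining lists did not pass the test either. Vascular lists had means of 0.05 for 22 basement membrane and matrix genes (adjusted p = 0.912), 0.01 for 24 genes of TGF-beta signaling and endothelial-to-mesenchymal transition (0.909), -0.05 for 20 Notch pathway genes (0.473) and -0.03 for 20 genes of vascular tone (0.566). The matrix genes Nid1 and Bgn differed by 0.85 (SE 0.35) and 0.56 (SE 0.26), and by 0.42 and 0.33 without diabetic replicate 1. The Notch targets Nrarp and Hey1 differed by -0.35 (SE 0.15) and -0.45 (SE 0.26), the latter by -0.23 without diabetic replicate 2. Inflammatory and stress lists had means of 0.15 for 27 immediate-early genes (adjusted p = 0.0759), 0.12 for 20 NF-kB response genes (0.31), 0.13 for 24 interferon response genes (0.314) and 0.12 for 15 p53 target and senescence genes (0.473). For 7 MHC class II presentation genes the mean was 0.11 (adjusted p = 0.912), for 20 hypoxia response genes 0.02 (0.904) and for 12 heat shock genes -0.04 (0.912). Nfkbie, an inhibitor of NF-kB, differed by 0.65 (SE 0.18). The hypoxia genes with the smallest p-values went both ways, with 0.83 (SE 0.24) for Hilpda, which coats lipid droplets, and -1.19 (SE 0.42) for Ddit4, a stress-induced inhibitor of mTOR, which differed by -0.70 without diabetic replicate 3. Redox and insulin lists had means of 0.21 for 7 NADPH oxidase genes (adjusted p = 0.349), -0.04 for 25 antioxidant genes (0.312) and -0.0031 for 22 insulin signaling genes (0.909). Sod2, the mitochondrial superoxide dismutase, differed by -0.42 (SE 0.15) and Gclm, of glutathione synthesis, by -0.39 (SE 0.19). Metabolic lists had means of 0.13 for 15 glycolysis genes (adjusted p = 0.137), -0.03 for 15 cholesterol synthesis genes (0.515) and 0.07 for 50 nuclear genes of oxidative phosphorylation (0.366). The lists watched for RNA quality had means of -0.02 for 10 mitochondrially encoded genes (adjusted p = 0.527) and 0.08 for 52 ribosomal protein genes (0.139). Adjusted over the list alone, 0 members of any list but the sinusoidal one passed, and with an estimated correlation the smallest adjusted p over all 36 lists was 0.383. The mean, the median and the direction given by camera did not share a sign for niche, insulin signaling, TGF-beta, erythroid, basement membrane and MHC class II genes.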

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

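The test of the second Rabggtb probe set, the tests of the sinusoidal and arteriolar pattern, the splits of single lists and the tests of the immunoglobulin pattern were chosen after the values were seen; the splits for the counts of genes and lists and the count of widely separated probe sets were set beforehand. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes higher in diabetes, as did every other (10 of 10 gave as many), and 1 gene lower, where the highest of the other splits gave 0 (1 of 10 gave as many). It gave 8 shifted lists, where the highest of the others gave 10 (2 of 10 gave as many). For each of the 8 lists alone, a difference as large as the real one was reached by 1 of 10 splits for the sinusoidal (0.48, highest other 0.33), monocyte (0.31 and 0.23), neutrophil (0.31 and 0.24) and cell cycle means (0.14 and 0.13), by 2 of 10 for the adhesion (0.32 and 0.36) and fatty acid means (0.22 and 0.30), and by 3 of 10 for the arteriolar (0.29 and 0.50) and unfolded protein response means (0.22 and 0.29).

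Among probe sets outside the gene comparison, 3 with no gene name here lay over 2 log2 units higher on every diabetic array than on any nondiabetic array. Such wide gaps were as common in other splits of the arrays. Over all probe sets the real split had 4, the highest other split had 7, and 6 of 10 splits, the real one included, had as many. Probe set 17208129 differed by 2.83, with diabetic values of 6.69, 7.01 and 7.14 against 4.18, 4.47 and 3.68. Probe set 17284490 differed by 4.12, with 9.36, 8.55 and 10.37 against 5.06, 4.72 and 6.14. Probe set 17459341 differed by 3.75, with 10.06, 10.15 and 10.42 against 4.40, 7.53 and 7.43. The number 17284490 lies between those of the probe sets of Ighm, 17284360, and of an immunoglobulin heavy chain segment, 17284564. The number 17459341 lies between those of the kappa segment probe sets 17459324 and 17459347. Such segments varied widely between arrays of the same group, as given below. Whether 17284490 and 17459341 measure immunoglobulin segments was not tested.

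The probe set of Rabggtb alone was at 3.32 ± 0.26 on the diabetic and at 7.75 ± 0.24 on the nondiabetic arrays (SD, n = 3 each), with every diabetic array below every nondiabetic one. The diabetic values may be background alone, so the size of the fall is a bound. A broad batch or genotype difference that follows the groups was expected to leave more widely separated probe sets in the real split than in any other. The real split had 4 with a gap of over 2 and the highest of the other splits had 7, so no excess of such wide gaps followed the groups. This count cannot see a smaller difference, or one at few places in the genome, so a batch or genotype difference stays open. A fall of the whole transcript and a change of the probed part alone cannot be told apart: the second probe set differed by -0.29, but it also names Snord45c, so its signal may come from either. A difference brought about by diabetes, and one in the mice unrelated to it, both stay open and were not tested.

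The sinusoidal mean was higher and the arteriolar mean lower in diabetic cells, and the difference between these means was -0.10 ± 0.11 in diabetic and -0.87 ± 0.16 in nondiabetic arrays (SD, n = 3 each; exact p = 0.1, the smallest possible). A different share of endothelial cells in the sorts would move these lists along with the pan-endothelial list, which shares 0 genes with either. This expectation was written after the means of these lists were seen. The group differences that follow were thus already known and are no independent test. The sinusoidal minus pan-endothelial mean was higher in diabetes by 0.52 (SE 0.10) and the arteriolar minus pan-endothelial mean lower by 0.25 (SE 0.09), each with the arrays of the groups apart, which argues against it as the whole cause; for the arteriolar list this is not firm, at 0.21 (SE 0.14) lower without diabetic replicate 1 and 0.20 (SE 0.13) without diabetic replicate 3. RNA of resident macrophages would leave the 11 sinusoidal genes that macrophages do not share unmoved; the group mean was higher by 0.58 (SE 0.21) in diabetes, with every diabetic array above every nondiabetic one, which argues against it as the whole cause; leaving out diabetic replicate 1 gave 0.38 (SE 0.09) and leaving out diabetic replicate 2 gave 0.64 (SE 0.34), under 2 standard errors. A list of 8 macrophage genes decides nothing here, since 5 of them were too faint to be tested. A larger share of sinusoidal cells among the sorted endothelium and a change of expression within sinusoidal cells cannot be told apart, since the SD of the members' differences was 2.12 times their mean standard error, between the values set for each. Diabetes itself stays a candidate cause of either, as a hypothesis, since the pattern was found and tested on the same 6 arrays.

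Immunoglobulin variable segments differed between arrays of the same group, and the design gives no biological group for this, so no biological explanation was tested between groups. Probe set 17467398, of a kappa segment, ranged from 3.90 to 10.88 over the arrays, 17284564, of a heavy chain segment, from 2.96 to 9.76 and 17467489, of a kappa segment, from 3.56 to 11.65; these are given after their values were seen. The tests took the 15 probe sets, of 13 segments, with a value over 9 on at least 1 array. Noise of probe sets of this brightness is argued against, since their median within-group SD was 1.33, where sets of other probe sets that also passed 9 on some array, matched on the highest value, had a median of 0.19 and 0.30 at the upper end of their middle 95%. All 19 such probe sets, bright or not, had a median of 1.33, against 0.19 and 0.26 for sets matched on mean. With 1 probe set for each of the 13 segments the median was 1.33, against 0.19 and 0.31. A different amount of plasma cell RNA per array was expected to move the segments together. Their deviations had a mean pairwise correlation of 0.0134, or 0.0604 with 1 probe set per segment, so no shared rise and fall was seen. With few clones per sort the amount could differ without such a shared movement, so this does not decide whether it differed. The mean of the plasma cell genes chosen after seeing the data ran from 6.38 to 7.53 over the arrays. A small number of antibody-secreting clones carried into each sort remains open. Of the 15 probe sets, picked for passing 9 on some array, 6 (40%) were under 6 on another, 5 of 13 with 1 per segment. So were 7 of the 1250 other probe sets picked the same way. Ighm stayed between 12.38 and 12.89 and Jchain between 9.70 and 10.77. An endothelial gate is meant to remove such cells, yet the arrays of both groups held signal for these 2 genes.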

How the results depend on the processing

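The covariate fit was chosen after seeing the data, and the other alternatives were set beforehand. Genes higher in diabetes stayed at 0 under every alternative run. Genes lower numbered 1 except with the filter at the 60th percentile and without nondiabetic replicate 3, where they numbered 0, so that leaving out single arrays gave 0 to 1; there the Rabggtb mean of 5.53 and 5.04 lay under the limits of 5.98 and 5.08, and it was not tested. Where tested, the measured Rabggtb difference lay between -4.58 and -4.34 and its adjusted p between 4.14e-05 and 0.00877; with diabetic values under the dim limit, this range does not give the precision of the size of the fall. Shifted lists, 8 as reported, numbered 4 with the filter at the 60th percentile, which tests fewer genes, 0 with an estimated correlation, 0 by fry (smallest adjusted p = 0.107), and 5 to 12 with single arrays left out, 5 without nondiabetic replicate 1 and 12 without nondiabetic replicate 3; the cause was not tested. They numbered 6 to 10 under the other alternatives, and 8 with the covariate. All 8 lists kept their direction under every alternative. At an unadjusted p under 0.05, the 566 genes became 1132 with array weights, 1054 with every probe set, 914 with no filter and 370 at the 60th percentile.

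The replicate numbers gave no sign of pairing the arrays, which does not exclude a pairing. Same-numbered arrays deviated together with correlations of -0.04, -0.06 and 0.02, and only replicate 3 correlated best with its own number. With the replicate block there were 0 genes higher, 1 lower and 9 lists.

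Of 112 named genes 102 kept their sign under every alternative that tested them, and none but Rabggtb had an adjusted p under 0.05 in any. The 10 others differed by -0.27 (Rgs5) to 0.23 (Jchain) as reported, and for each reversal the cause was not tested. After quantile normalization Ppbp was -0.0080, Insr -0.0028 and Il6 -0.036. With array weights Jchain was -0.088, Ppbp -0.012, Insr -0.033 and Mcpt8 0.056, and with the covariate Csf1 was -0.013 and Il6 -0.020. Leaving out single arrays gave -0.28 to 0.17 for Car1, -0.13 to 0.24 for Csf1, -0.26 to 0.20 for Egr1, -0.087 to 0.20 for Icam1, -0.14 to 0.30 for Il6, -0.10 to 0.10 for Insr, -0.10 to 0.16 for Mcpt8, -0.22 to 0.32 for Ppbp, -0.73 to 0.12 for Rgs5, and -0.27 to 0.071 for the mean of the pan-endothelial list. Of the 102, 51 moved by over 1.5 times under some alternative. Those with a value in the report ranged from -0.93 to -0.46 for Tmem47, -1.13 to -0.59 for Igfbp3, -0.58 to -0.11 for Rrm2, 0.33 to 0.84 for Lcn2, 0.27 to 0.71 for Cpt1a, 0.11 to 0.55 for Ly6c2, -0.45 to -0.19 for Ptprb, 0.062 to 0.57 for Mmrn2, -0.46 to -0.14 for Cxcl12, -0.51 to -0.0012 for Kitl, 0.56 to 1.20 for Vcam1, 0.039 to 0.20 for Gpx1, 0.072 to 0.26 for Nos3, 0.42 to 1.19 for Nid1, 0.33 to 0.72 for Bgn, -0.75 to -0.23 for Hey1, -1.53 to -0.70 for Ddit4 and -0.46 to -0.25 for Gclm; most of these ends came from leaving out a single array. Genes under the dim limit of 5.07, 8872 of 22180, were too faint to be tested.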

Other observations

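Genes of antibody-secreting cells varied between the arrays, and their difference between the groups was not settled. The list held 11 genes chosen after seeing the data, 1 of which the B lymphoid list also holds and 0 the unfolded protein response list. The list mean was 7.16 ± 0.41 in diabetic and 6.73 ± 0.35 in nondiabetic arrays (SD, n = 3 each), a difference of 0.44 (SE 0.31) with an exact p = 0.2, two-sided, where 0.1 is the smallest possible. The difference was 0.25 without diabetic replicate 1 and 0.27 without nondiabetic replicate 1. Camera gave p = 0.183 with an estimated correlation and p = 0.000164 at the preset one, which carries little weight for genes picked after their values were seen. The 3 members with the largest differences follow. Tnfrsf17, the receptor BCMA of plasma cells, was at 5.88, 5.89 and 7.61 on the diabetic and 4.83, 5.90 and 6.20 on the nondiabetic arrays, and Slamf7 at 8.24, 7.31 and 7.63 against 6.57, 6.96 and 7.82. Fkbp11, a chaperone of secretory cells, was at 6.51, 5.91 and 5.70 against 5.60, 5.43 and 5.33. The smallest differences were 0.10 for Prdm1 and 0.23 for Jchain.

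Small nucleolar RNA genes varied widely between arrays. The median within-group SD of 73 such genes was 0.60, against 0.20 for the other genes. The SD of their log2 differences between the groups was 0.74, against 0.22. Of the 73, 44 were bright enough to be tested, and the comparison with the other genes was not matched on brightness. Of the probe sets with no gene name here, 331 (2.07%) differed by over 1.5 between the group means, against 27 (0.107%) of the named probe sets.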
